A study of Rattus norvegicus with 15 samples.

How the data were processed

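RNA was taken per the labels from rat aortic SMC with an RNeasy kit and DNase I treatment, and polyA libraries were made with a TruSeq Stranded mRNA kit. The deposited values are TPM calculated by the authors, in 1 table of 32623 gene entries with a column for each of 15 libraries. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Each column was checked to add up to the same total with no further scaling between libraries. TPM keep no sequencing depth, so no counting interval was calculated. The 4 columns of group means in the table were not used. Of the entries, 26 had symbols turned into dates by a spreadsheet and were kept under their Ensembl identifiers. Symbols present more than once carry a number after the symbol.

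Genes were kept when TPM was at least 1 in at least 3 of the 15 libraries, which left 12207 and excluded 20416. A pseudocount of 1 was added before log2. A linear model with 1 mean per group was fitted to all libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean expression (eBayes with trend). Libraries with the same number in different groups were not paired. The 5 comparisons were Myocd-LSD1 against control, Myocd-LSD1NF against control, Myocd-LSD1 against Myocd-LSD1NF, PDGF-BB against control and Myocd-LSD1 against PDGF-BB. Genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 were called, and those with a log2 fold change of at least 1 in size were counted as changed at least 2-fold. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

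A total of 26 gene lists were written from general knowledge. They cover contractile and SMC identity genes, serum response factor and cytoskeleton genes, H3K4 methylation enzymes, collagens and elastic fibres, matrix remodelling, adhesion, proliferation, early growth factor response, inflammation, interferon response, TGF-beta and BMP response, cholesterol synthesis, glycolysis and hypoxia, amino acid and unfolded protein response, p53 targets and stem cell factors. Further lists hold markers of endothelial, fibroblast, leukocyte, cartilage and bone, adipocyte, striated muscle, neural, and epithelial and mesothelial cells, ribosomal protein genes and mitochondrially encoded genes. List members not matched by symbol, among them Col1a2, Pecam1, Rps6 and Mt-co3, were not used here. Each list was tested with limma camera (preset correlation 0.01, adjusted over the 26 lists of a comparison), beside camera with a correlation estimated from the data and the rotation test fry. Called members were counted over all genes and adjusted over the list alone. Counts are out of the members matched by symbol that passed the filter on low genes. These were few for some lists, with 7 of 24 stem cell factors and 6 of 25 striated muscle markers. They were 5, 4, 3 and 6 of 20 endothelial, leukocyte, neural, and epithelial and mesothelial markers. The comparisons, tests, lists and alternatives were chosen before the data were examined, except where stated.

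The genes named were set by a rule. For each comparison it takes the 6 largest rises and the 6 largest falls (3 and 3 for Myocd-LSD1 against PDGF-BB) among called genes with a mean of at least 5 TPM in the higher group, no overlap between the values of the groups and a symbol that is not a locus identifier. It adds Myocd, Kdm1a, Acta2, Tagln, Myh11 and Cnn1 in every comparison. From each list with at least 3 called members or a camera adjusted p under 0.05 it takes up to 3 called members with the largest change and 1 in the other direction, and from other lists up to 2. For overlaps it takes 5 genes per pair of directions. Not all genes that the rule takes are reported here. Genes outside the rule are said to have been chosen after their values were seen.

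Alternatives were pseudocounts of 0.1 and 5, no filter on low genes, a filter at a mean of 5 TPM, median-of-ratios scaling, quantile normalization, the replicate number as a block, limma array weights, a fit of the compared groups alone, and leaving out each library in turn. Chosen after seeing the data were leaving out Myocd-LSD1 libraries 2 and 4 together and leaving out a run of neighbouring genes. For the overlaps, unchanged groups were simulated against the same 4 controls in 100 draws, and the controls were split 2 and 2 in all 6 ways. The procedure was tested on simulated data with the groups' sizes, where 200 of 12207 genes were changed. The changed genes were drawn only from those averaging above 5 TPM on the log scale. Simulated genes varied independently, with the same spread in every group, so the rates below do not cover lower genes, correlated genes or groups of unequal spread. The test called 38.8% to 49.3% of genes changed 1.5-fold, 76.1% to 92.5% of those changed 2-fold and 92.4% to 97.0% of those changed 4-fold, with 5 to 11 false calls in a comparison.

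Gene order was taken from a RefSeq annotation of the rat assembly GRCr8 by symbol, which matched 10614 of the 12207 tested genes. It was used only for which genes neighbour each other, since the authors' build is not stated, and no coordinates are given. Runs of neighbouring genes used 8866 of these, those with a mean of at least 5 TPM.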

Results

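RNA-seq was performed on cultured rat aortic smooth muscle cells (SMC) in 4 groups. The control group and the lines named Myocd-LSD1 and Myocd-LSD1NF held 4 libraries each, and SMC treated with PDGF-BB held 3. Myocd-LSD1 is a fusion of myocardin, the coactivator of serum response factor that drives contractile genes, with LSD1, the histone demethylase encoded by Kdm1a. Per the series design it was used to remove H3K4me2, a histone mark of active regulatory regions, from SMC genes. What NF stands for is not given in the sources used here. Platelet-derived growth factor BB (PDGF-BB), a mitogen for SMC, was given at 30 ng/ml for 24 h after 48 h of starvation, and cells were starved for 72 h in all before harvest.

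The deposited values were TPM, transcript abundances normalized for length and to the same total in each library, which keep no sequencing depth, so the depth behind each value is unknown. Between 11306 and 11702 genes reached 1 TPM in a library. Libraries of 1 group correlated at 0.961 to 0.988 on the log scale. This range does not set Myocd-LSD1NF apart from control. Myocd-LSD1NF 1 to 3 correlated with the controls at 0.963 to 0.985, and Myocd-LSD1NF 4 with its own group at 0.963 to 0.967. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels below are mean TPM ± SD (n = 4 libraries, n = 3 for PDGF-BB). Log2 fold changes are given ± SE on the log2(TPM + 1) scale, which understates the change of low genes, and adjusted p-values come from limma.

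The genes of the 2 fusion partners were read first. Myocd stood at 27.8 ± 1.96 TPM in control, 34.6 ± 13.7 in Myocd-LSD1NF, 19.7 ± 4.33 in PDGF-BB and 0.310 ± 0.186 in Myocd-LSD1. Kdm1a stood at 55.1 ± 3.48, 54.1 ± 5.73, 70.6 ± 7.48 and 64.6 ± 4.11 TPM. Neither gene was higher by the test in the Myocd-LSD1 line than in control (adjusted p = 0.0874 for Kdm1a), so these values do not check the presence of the fusion. Whether reads of a fusion transcript were counted to either gene is not given in the sources used here.

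**Figure D1:**
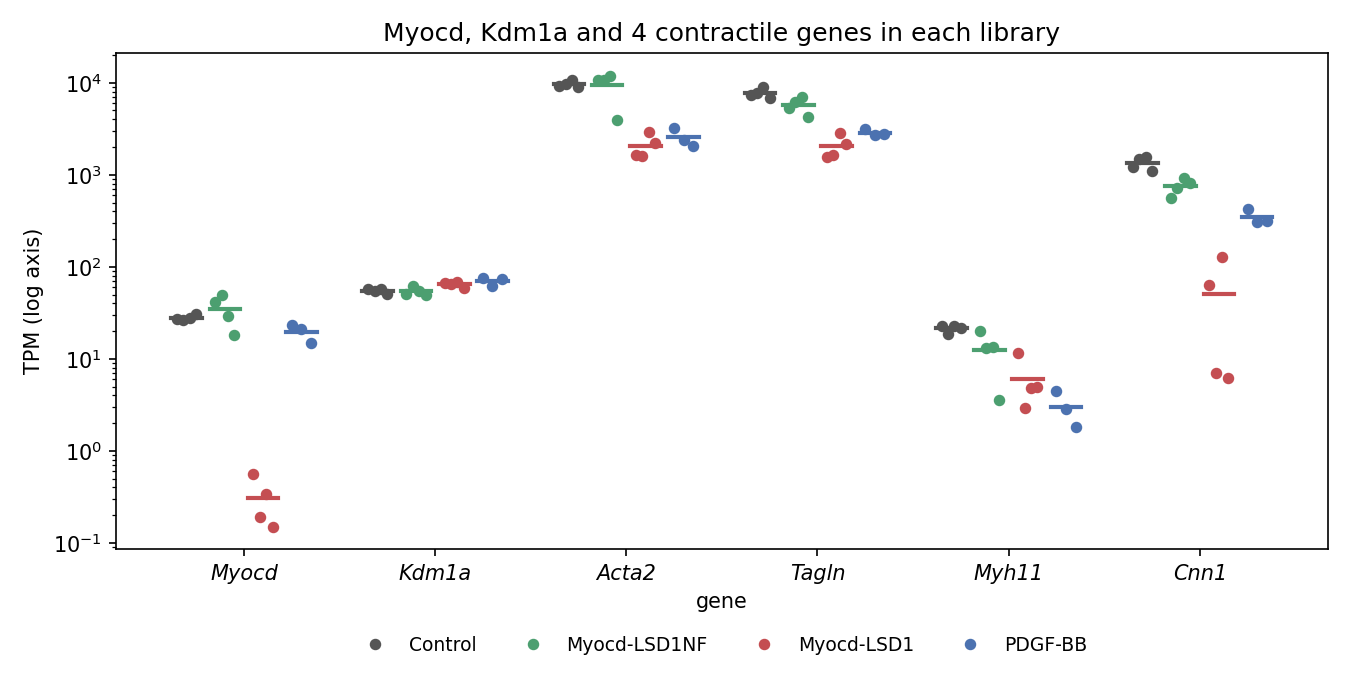
TPM of Myocd, Kdm1a, Acta2, Tagln, Myh11 and Cnn1 on a log axis, 1 point per library and a bar at each group mean. Myocd averages 0.310 TPM in Myocd-LSD1 against 27.8 in control, and Acta2 2077 against 9718.

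The Myocd-LSD1 line was compared with control SMC to ask how their transcriptomes differed. In this and the Myocd-LSD1NF comparison, an effect of the fusion cannot be told apart from other differences between the line and control SMC. Contractile genes were far lower. Acta2, smooth muscle actin, fell from 9718 ± 772 to 2077 ± 611 TPM (log2 fold change -2.27 ± 0.31, adjusted p = 4.80e-05, n = 4 and 4). Tagln, transgelin, fell from 7679 ± 901 to 2045 ± 586 TPM, and Cnn1, calponin, from 1339 ± 208 to 51.0 ± 57.7 TPM. Myocd itself fell by 4.47 ± 0.24 on the log2 scale (adjusted p = 4.73e-09) and Myh11, smooth muscle myosin, fell by 1.80 ± 0.41 (adjusted p = 0.00329). Elastin (Eln), the main elastic fibre protein of the aorta, fell from 13039 ± 1919 to 253 ± 238 TPM.

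Of 30 contractile and SMC identity genes, 28 fell, 1 rose and 1 did not pass. Adjusted over the list alone, 29 fell and 1 rose. Myl9, a myosin light chain, fell by 5.20 ± 0.40 on the log2 scale, Itga8, an integrin of SMC, had a log2 fold change of -5.15 ± 0.35, and Des, desmin, rose from 0.870 ± 0.544 to 5.51 ± 1.61 TPM. The list fell as a set with limma camera (median log2 fold change -2.52, adjusted p = 1.58e-21; adjusted p = 0.146 with an estimated correlation). Of 25 serum response factor and actin cytoskeleton genes, 15 fell and 1 rose, with the same counts adjusted over the list alone. They included Ankrd1 (log2 fold change -3.66 ± 0.97), Filip1l (-2.28 ± 0.30) and Vcl, vinculin (-1.46 ± 0.22), and against them Thbs1, thrombospondin (0.99 ± 0.22). This list fell as a set (adjusted p = 0.000625; adjusted p = 0.502 with an estimated correlation). Among 6 cardiac and skeletal muscle markers 5 fell, or 6 adjusted over the list alone, led by Myh3 (-3.59 ± 0.65) and Acta1 (-2.56 ± 0.59). The set fell (adjusted p = 0.00102; adjusted p = 0.314 with an estimated correlation).

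The 4 Myocd-LSD1 libraries were unequal in these genes and beyond them. Over all tested genes libraries 2 and 4 correlated at 0.987 and libraries 1 and 3 at 0.981, against 0.961 to 0.978 for the other pairs. Libraries 2 and 4 held 167 identical TPM values, the other pairs 68 to 92. The p-values treat the 4 libraries as independent, which the labels do not settle. Cnn1 read 63.2, 7, 128 and 6.24 TPM in libraries 1 to 4. Eif2s3y, a Y-linked housekeeping gene chosen after its values were seen, read 143, 47.8, 179.9 and 79.4 TPM in the same order, against 140.1 to 170.0 TPM in the 4 controls. Without libraries 2 and 4, an alternative chosen after seeing the data, 2984 genes passed.

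The largest falls were in Rgs4 and Rgs5, regulators of G protein signalling, from 659 ± 129 to 0.357 ± 0.339 TPM and from 639.6 ± 483 to 0.620 ± 0.780 TPM. They were followed by Nid1, a basement membrane glycoprotein (191 ± 23.6 to 0.107 ± 0.106 TPM), Igfbp2, a binding protein of insulin-like growth factors (1571 ± 368 to 47.0 ± 52.9 TPM), and Pcdh7, a protocadherin (109.9 ± 10.2 to 0.225 ± 0.373 TPM). The largest rises were in Uba1y, a Y-linked ubiquitin-activating enzyme, from 0.0125 ± 0.0250 to 171 ± 100.0 TPM, Wfdc18 (1.06 ± 0.474 to 293 ± 298 TPM), Ms4a18 (0.115 ± 0.0896 to 81.5 ± 46.2 TPM) and Akr1b10, an aldo-keto reductase (2.21 ± 0.663 to 202 ± 40.5 TPM). Ppp1r1b, a phosphatase inhibitor, rose from 0.158 ± 0.123 to 73.3 ± 28.9 TPM and Fam25a from 0.362 ± 0.327 to 78.1 ± 39.2 TPM. In these genes, and in Eln, which had the sixth largest fall, adjusted p-values ran from 1.47e-10 to 0.000161. Uba1y read 237, 66.3, 274 and 107 TPM in libraries 1 to 4.

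Other lists held calls without passing camera. In the collagen and elastic fibre list 10 genes fell and 6 rose of 23 (the same adjusted over the list alone), with Postn, periostin, at -5.08 ± 0.38, Mfap5 at -3.83 ± 0.73 and Col6a3 at 3.33 ± 0.52. Of 28 early growth factor response genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), led by Dusp6 (3.19 ± 0.47), a phosphatase of the ERK pathway, Fosl1 (2.78 ± 0.65) and Dusp5 (2.24 ± 0.37), with Spry4 lower (-0.75 ± 0.17). Of 25 glycolysis and hypoxia genes 10 rose and 1 fell (11 and 1), with the lactate carrier Slc16a3 at 1.79 ± 0.46. Of 25 amino acid and unfolded protein response genes 11 rose and 2 fell (12 and 2), with the serine synthesis enzyme Psat1 at 2.17 ± 0.44. Of 24 TGF-beta and BMP genes 6 rose and 4 fell (7 and 4). Tgfbi rose from 5.27 ± 2.44 to 216 ± 97.0 TPM and the ligand Tgfb3 fell from 470.4 ± 56.2 to 82.0 ± 6.86 TPM. Klf4 and Klf5, factors of phenotypic switching in SMC, rose by log2 1.82 ± 0.54 and 1.45 ± 0.31. With Prom1 (3.27 ± 0.34) they were among 4 of 7 tested stem cell factors that rose (4 adjusted over the list alone). The list held 24 genes. The rest were not matched or did not pass the filter, which a gene on only in Myocd-LSD1 does pass.

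The remaining lists had these counts of genes higher and lower, with those adjusted over the list alone in parentheses. Matrix remodelling had 6 and 3 of 17 (7 and 3), with Timp1 (2.01 ± 0.26) and Timp3 (405 ± 44.1 to 77.7 ± 78.0 TPM) on either side. Adhesion had 7 and 10 of 25 (7 and 11), with Itga11 (2.20 ± 0.45) and Cdh11 (-5.29 ± 0.54). Inflammation had 3 and 3 of 15 (3 and 3), interferon 3 and 4 of 23 (3 and 4), cholesterol 0 and 7 of 25 (0 and 6), and p53 targets 2 and 6 of 22 (2 and 7), with Cdkn1a lower (-1.56 ± 0.28). H3K4 enzymes had 2 and 1 of 23 (1 and 0), proliferation 2 and 0 of 29 (0 and 0), ribosomal proteins 0 and 0 of 26 (0 and 0), and mitochondrially encoded genes 0 and 1 of 12 (0 and 0). Without Myocd-LSD1 libraries 2 and 4, left out together after the data were seen, the proliferation list turned direction and was higher as a set (camera adjusted p = 0.0210 at the preset correlation). The correlation estimated for this list from all libraries was 0.84, at which the reported fit gave a camera adjusted p of 0.980. For markers of other cell types, fibroblast genes had 3 and 5 of 13 (4 and 5), cartilage and bone 6 and 4 of 15 (6 and 5), adipocyte 0 and 3 of 10 (0 and 2), and endothelial 2 and 3 of 5 (2 and 3). Leukocyte markers had 3 and 0 of 4 (3 and 0), neural 1 and 1 of 3 (1 and 1), and epithelial and mesothelial 3 and 1 of 6 (3 and 1), led by mesothelin, Msln, at 4.32 ± 0.68. For the interferon, endothelial, fibroblast and cartilage lists the median and the mean log2 fold change had opposite signs, and the interferon and neural medians changed sign between scalings.

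In total 3936 of 12207 genes passed (2062 higher, 1874 lower) in Myocd-LSD1 against control, of which 1475 changed at least 2-fold (695 higher, 780 lower). The split was 2033 higher and 2180 lower under median-of-ratios scaling, 2217 and 2102 under quantile normalization, and 2473 and 2982 with array weights. Of 26 lists 3 passed camera, 0 with an estimated correlation and 10 with fry, which tests only whether a list's genes moved 1 way.

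**Figure D2:**
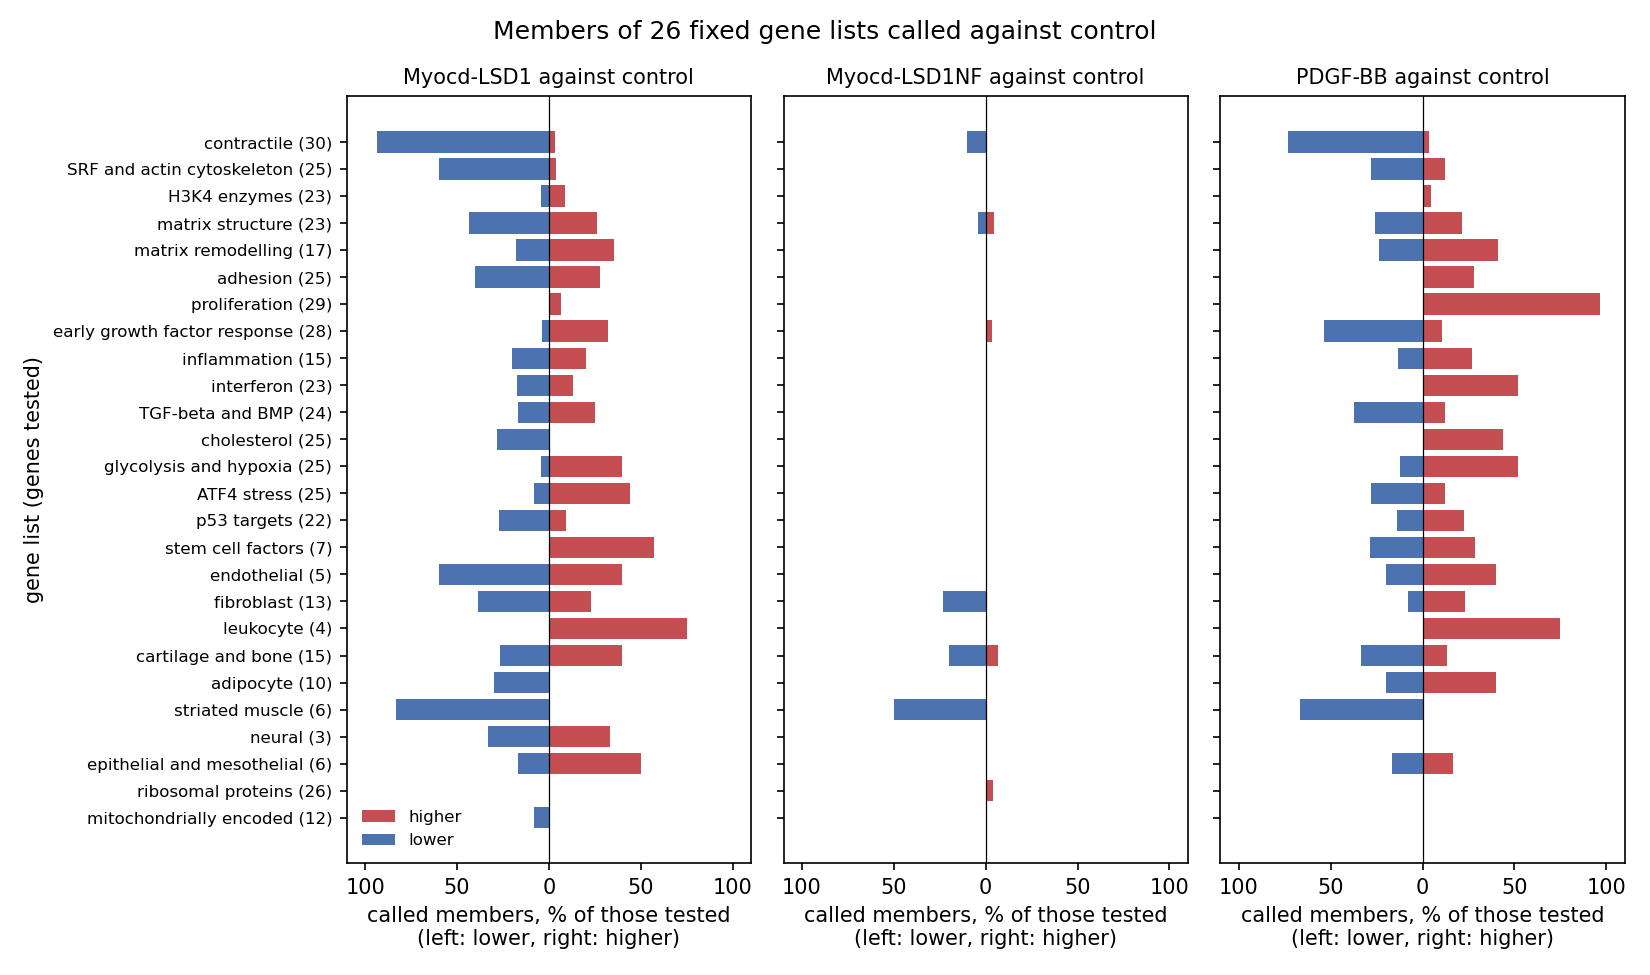
Percent of tested members of each of 26 fixed gene lists called against control, higher to the right and lower to the left, in Myocd-LSD1, Myocd-LSD1NF and PDGF-BB. Among contractile genes 28, 3 and 22 of 30 fell, and among proliferation genes 2, 0 and 28 of 29 rose.

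Myocd-LSD1NF was compared with control in the same way. The main contractile markers did not pass the test, though the means of Tagln, Myh11 and Cnn1 were lower. Acta2 averaged 9359 ± 3635 TPM against 9718 ± 772 in control (adjusted p = 0.839, n = 4 and 4), with library 4 at 3979 TPM, Tagln 5697 ± 1153 against 7679 ± 901 TPM (0.296). Myh11 averaged 12.5 ± 6.73 against 21.5 ± 2.07 TPM (0.287) and Cnn1 758 ± 152 against 1339 ± 208 TPM (0.617). The spread for Cnn1 was pooled with Myocd-LSD1, where it ranged from 6.24 to 128 TPM, so its missed call does not show an unchanged level. Acta2 lies in a run of neighbouring genes, given below, that stood above control in libraries 1 to 3. Myocd and Kdm1a did not pass either (adjusted p = 0.716 and 0.920). The largest falls were in Pdpn, podoplanin, from 46.0 ± 18.8 to 1.35 ± 0.904 TPM, Aebp1, a matrix-associated protein, from 15.3 ± 3.46 to 0.080 ± 0.0408 TPM, and Jup, junction plakoglobin, from 14.6 ± 4.75 to 0.412 ± 0.387 TPM. Nid1, the matrix glycoprotein Fbln1 and Actg2, enteric smooth muscle actin, had log2 fold changes of -3.34 ± 0.76, -3.16 ± 0.45 and -3.15 ± 0.41 (adjusted p = 0.0320, 0.00147 and 0.000739).

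Dusp5 rose from 17.6 ± 4.30 to 64.8 ± 12.5 TPM, the transcription factor Tfap2a from 4.36 ± 2.22 to 13.6 ± 5.04 TPM and Npy1r, a neuropeptide receptor, from 1.69 ± 0.379 to 6.27 ± 0.732 TPM. The other 3 of the 6 largest rises were copies of duplicated symbols, whose values are uncertain. Rpl32_2 was listed at 0 in all 4 controls and at 135, 287, 450.1 and 254 TPM in Myocd-LSD1NF. Trappc2b_2 was listed at 0 in all 4 controls and at 9.91, 11.5, 4.5 and 6.47 TPM, and Cttn_2 averaged 13.5 ± 2.08 and 72.8 ± 23.0 TPM.

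Of 30 contractile genes 3 fell, Actg2, Myl9 (-2.80 ± 0.40) and Tpm2 (-0.87 ± 0.19), or 4 adjusted over the list alone, and the list fell as a set (limma camera adjusted p = 0.000215; adjusted p = 0.577 with an estimated correlation). Of 6 striated muscle markers 3 fell (Acta1, Ckm and Tnnt3), or 4 adjusted over the list alone, and that list fell too (adjusted p = 0.000215; adjusted p = 0.182 with an estimated correlation). Proliferation (adjusted p = 0.000215), early growth factor response (0.000353), inflammation (0.00159), cholesterol (0.000218), TGF-beta and BMP (0.0227), amino acid and unfolded protein response (0.0219) and ribosomal protein genes (0.0418) were higher as sets. Adjusted p = 0.736, 0.577, 0.182, 0.718, 0.565, 0.736 and 0.845 with an estimated correlation, in the same order. The TGF-beta, amino acid and ribosomal lists also missed the threshold under median-of-ratios scaling (adjusted p = 0.0647, 0.0578 and 0.0899). Without Myocd-LSD1NF 4 the contractile, cholesterol, TGF-beta and amino acid lists no longer passed (adjusted p = 0.104, 0.172, 0.204 and 0.269), nor did the early growth factor list without control 2 (0.0520). Without control 1 or control 2 the TGF-beta (0.125 and 0.0783), amino acid (0.103 and 0.415) and ribosomal lists (0.336 and 0.717) did not pass. The ribosomal list turned direction without Myocd-LSD1NF 3 (adjusted p = 0.611). Only 2 single members of these 7 lists passed over all genes, Dusp5 and Rplp2 (0.78 ± 0.19), and 3 adjusted over the lists alone. Of fibroblast markers 3 of 13 fell (3, with 1 higher, adjusted over the list alone), led by Lum (-2.89 ± 0.43) and Ogn (-2.36 ± 0.55). Of cartilage and bone markers 3 of 15 fell and 1 rose (4 and 2 adjusted over the list alone), led by Col11a1 (-1.67 ± 0.27). Neither list passed camera.

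In all, 270 genes passed (58 higher, 212 lower), 150 of them at least 2-fold (23 higher, 127 lower), and 1917 had an unadjusted p under 0.05. Under median-of-ratios scaling the split was 103 higher and 214 lower, and under quantile normalization 95 and 175. A run of 506 neighbouring genes that includes Acta2, chosen after the data were seen, stood at a median log2 ratio to control of 0.35, 0.44, 0.16 and -0.06 in Myocd-LSD1NF libraries 1 to 4 as deposited. With each library centred on its median over the placed genes the ratios were 0.38, 0.42, 0.32 and -0.04. The run held 13 of the 32 higher calls that could be placed in gene order. The count of 270 fell to 109 without control 1, 112 without control 2, 128 without Myocd-LSD1NF 2 and 171 without control 3. It was 176 with the compared groups alone, 110 with a filter at a mean of 5 TPM and 919 (318 higher, 601 lower) with array weights.

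**Figure D3:**
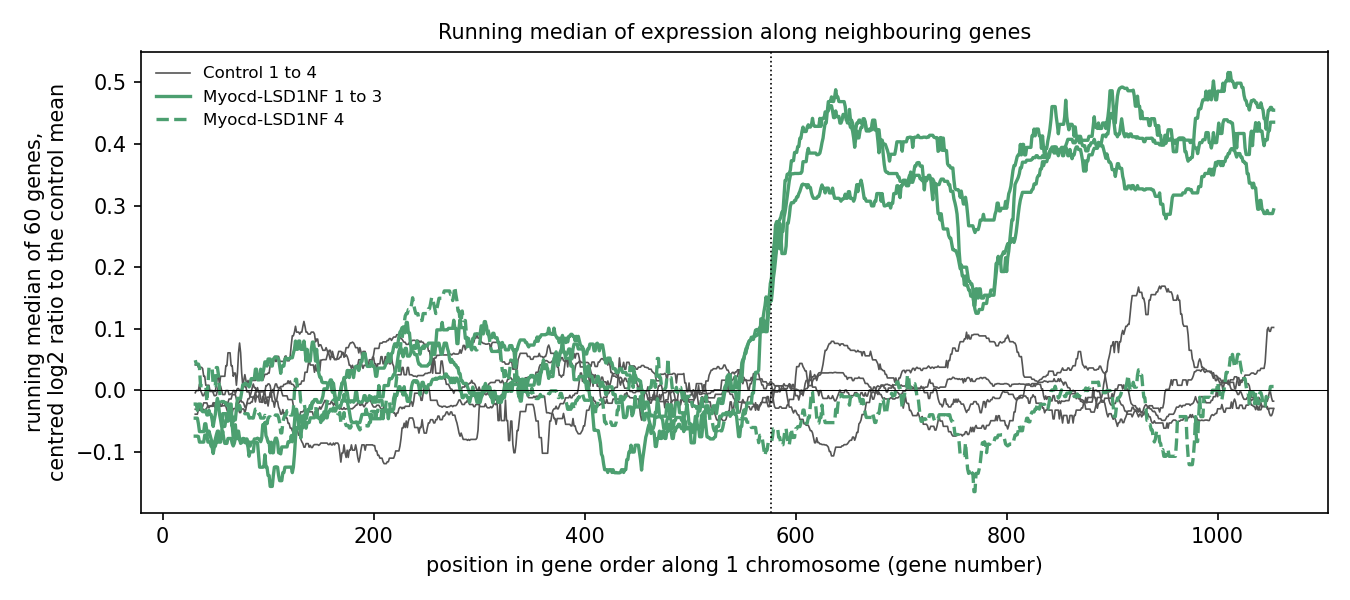
Running median over 60 neighbouring genes of the log2 ratio to the control mean, with each library centred on its median, in gene order along 1 chromosome (GRCr8 order), for the control and Myocd-LSD1NF libraries. Right of the dotted line lie 506 genes whose centred median is 0.38, 0.42 and 0.32 in Myocd-LSD1NF 1 to 3 and -0.04 in Myocd-LSD1NF 4 (0.35, 0.44, 0.16 and -0.06 without centring).

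Myocd-LSD1 and Myocd-LSD1NF were also compared directly, which tests whether the 2 lines differed. Acta2 was lower in Myocd-LSD1 (2077 ± 611 against 9359 ± 3635 TPM, log2 fold change -2.10 ± 0.31, adjusted p = 0.000123, n = 4 and 4), as were Tagln (2045 ± 586 against 5697 ± 1153 TPM), Cnn1 (-4.83 ± 0.69) and Myocd (-4.69 ± 0.24). Myh11 (-0.87 ± 0.41, adjusted p = 0.118) and Kdm1a (0.26 ± 0.10, adjusted p = 0.0531) did not pass. The largest differences downward were Rgs5 (0.620 ± 0.780 against 1019 ± 841 TPM), Rgs4 (0.357 ± 0.339 against 767 ± 313 TPM), Pcdh7 and Igfbp2. They also included the small proteoglycan Epyc (0.352 ± 0.246 against 107 ± 118 TPM) and Gucy1b3, a subunit of the nitric oxide receptor (0.0375 ± 0.0750 against 54.3 ± 23.6 TPM). Upward they were Uba1y, listed at 0 in all 4 Myocd-LSD1NF libraries, Tgfbi (216 ± 97.0 against 4.12 ± 6.87 TPM), Fam25a and Wfdc18, and also the Wnt modulator Sfrp2 (566 ± 64.3 against 9.83 ± 5.45 TPM) and heparanase, Hpse (91.1 ± 26.1 against 0.585 ± 0.469 TPM). Myocd-LSD1NF 4 stood apart from its group in several of these genes. It was higher in Rgs5 (2269 TPM against 468 to 749), Epyc (281 against 29.3 to 71.2), Tgfbi (14.4 against 0.560 to 0.850) and Wfdc18 (18.0 against 0 to 0.470).

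Of 30 contractile genes 24 were lower and 1 higher (25 and 1 adjusted over the list alone; limma camera adjusted p = 9.94e-19; adjusted p = 0.221 with an estimated correlation). Of 25 cytoskeleton genes 15 were lower and 1 higher (15 and 2 alone; adjusted p = 6.95e-06; adjusted p = 0.604 with an estimated correlation). Of 25 cholesterol genes 13 were lower, among them Tm7sf2 (-1.61 ± 0.18) and Sc5d (-1.24 ± 0.21), enzymes of sterol synthesis. In that list 1 was higher (15 and 1 alone; adjusted p = 1.54e-05; adjusted p = 0.742 with an estimated correlation). Mitochondrially encoded genes were lower as a set with 1 of 12 called, Mt-nd6, and 0 adjusted over the list alone (adjusted p = 0.0470; adjusted p = 0.742 with an estimated correlation and 0.108 under median-of-ratios scaling). They no longer passed without Myocd-LSD1 1 or 3 or Myocd-LSD1NF 1 or 4 (adjusted p = 0.145, 0.119, 0.104 and 0.0974). In the collagen and elastic fibre list 9 of 23 were lower and 5 higher (9 and 6 alone), with Eln at -4.97 ± 0.51, Postn at -4.81 ± 0.38 and Col6a1 at 3.98 ± 0.31. Of cartilage and bone markers 7 of 15 were higher and 3 lower (8 and 3 alone), with Col11a1 at 1.87 ± 0.27, Sox5, a chondrogenic factor, at 1.84 ± 0.26 and Mgp at -2.33 ± 0.55. Neither list passed camera.

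In this comparison 3877 genes passed (2331 higher and 1546 lower in Myocd-LSD1), 1286 at least 2-fold (684 and 602). Under median-of-ratios scaling the split was 2040 higher and 2131 lower, so the number of genes on either side depended on the scaling.

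PDGF-BB was compared with control SMC to measure the response to the mitogen. Cell cycle genes were higher in treated cells. Ccnd1, cyclin D1, rose from 35.6 ± 17.3 to 259 ± 112 TPM, Ccnb1, cyclin B1, from 18.6 ± 5.23 to 71.1 ± 3.15 TPM and Cdc20, an activator of mitotic exit, from 30.7 ± 3.63 to 112 ± 7.88 TPM (adjusted p = 0.00124, 0.00436 and 0.00156, n = 3 and 4). Contractile genes were lower, with Acta2 at 2554 ± 606 against 9718 ± 772 TPM (log2 fold change -1.95 ± 0.33, adjusted p = 0.000750), Tagln at -1.42 ± 0.22, Myh11 at -2.53 ± 0.44 and Eln at 1413 ± 84.9 against 13039 ± 1919 TPM. Cnn1 (-1.94 ± 0.74, adjusted p = 0.0655) and Myocd (-0.50 ± 0.26, adjusted p = 0.163) did not pass. The spread used for Cnn1 was pooled over all 4 groups, and in Myocd-LSD1, outside this comparison, it ranged from 6.24 to 128 TPM. Its missed call therefore does not show that Cnn1 was unchanged by PDGF-BB. Kdm1a rose by log2 0.35 ± 0.10 (adjusted p = 0.0208). It was the only gene called of 23 H3K4 enzymes. Adjusted over that list alone 0 were called, and 0 under median-of-ratios scaling, so the call of Kdm1a depended on the scaling. The median log2 fold change of all genes was 0.12 as deposited and 0.00 under median-of-ratios scaling, so list medians below are given relative to the median of all genes.

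Of 29 cell cycle genes 28 rose, also adjusted over the list alone (median 1.38 above that of all genes; limma camera adjusted p = 5.92e-09; adjusted p = 0.627 with an estimated correlation). Of 30 contractile genes 22 fell and 1, Synpo2, rose (24 and 1 adjusted over the list alone), led by Itga8 (-3.13 ± 0.38) and the calcium-binding protein Casq2 (-2.66 ± 0.27), with a relative median of -1.60 (adjusted p = 2.35e-17; adjusted p = 0.274 with an estimated correlation). Early growth factor response genes were lower at 24 h, with 15 of 28 down and 3 up (16 and 3 alone) and a relative median of -1.03 (adjusted p = 9.90e-07; adjusted p = 0.502 with an estimated correlation). Fosb fell from 639 ± 374 to 26.5 ± 30.3 TPM, Fos from 1547 ± 298 to 228 ± 260.2 TPM and Egr2 from 52.4 ± 35.6 to 5.55 ± 5.70 TPM, while Etv4 rose (2.29 ± 0.46). Of 24 TGF-beta and BMP genes 9 fell and 3 rose (10 and 3 alone), led by Id1, a BMP target (311 ± 129 to 13.9 ± 2.71 TPM), and Bmp6 (-3.23 ± 0.36), with a relative median of -0.57 (adjusted p = 0.000715; adjusted p = 0.391 with an estimated correlation).

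Metabolic lists rose. Of 25 glycolysis and hypoxia genes 13 rose and 3 fell (13 and 4 alone), with Pkm, pyruvate kinase, from 609 ± 69.0 to 2009.8 ± 188 TPM and Gapdh from 1019.8 ± 86.1 to 2753 ± 379 TPM. Vegfa was lower (-1.30 ± 0.29), and the list had a relative median of 0.45 (adjusted p = 0.0312; adjusted p = 0.627 with an estimated correlation). It no longer passed without control 2 or PDGF-BB 2 (adjusted p = 0.0508 and 0.0521). Of 25 cholesterol genes 11 rose (14 alone; relative median 0.52, adjusted p = 0.000715; adjusted p = 0.704 with an estimated correlation). Of 23 interferon response genes 12 rose (12 alone), led by Gbp2 (2.43 ± 0.51) and Mx2 (2.07 ± 0.59; relative median 0.64, adjusted p = 0.000715; adjusted p = 0.627 with an estimated correlation).

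Other lists fell. Of 6 striated muscle markers 4 fell (4 alone), led by Myh3 (-3.59 ± 0.70), with adjusted p = 0.000715 as a set and adjusted p = 0.335 with an estimated correlation. Of 25 amino acid and unfolded protein response genes 7 fell and 3 rose (8 and 4 alone), led by Atf3 (-4.18 ± 0.65; adjusted p = 0.0312; adjusted p = 0.784 with an estimated correlation and 0.147 under median-of-ratios scaling). This list no longer passed without control 4, PDGF-BB 1 or PDGF-BB 2 (adjusted p = 0.465, 0.135 and 0.0536). Of 15 cartilage and bone markers 5 fell and 2 rose (6 and 2 alone), with Matn3 at -2.77 ± 0.37 and osteopontin, Spp1, at 1.02 ± 0.36 (adjusted p = 0.0124; adjusted p = 0.502 with an estimated correlation and 0.0911 under median-of-ratios scaling). The cytoskeleton list had 7 of 25 lower and 3 higher (8 and 3 alone), with Cyr61 at -1.96 ± 0.40 and Ctgf at -1.04 ± 0.22 (adjusted p = 0.0103; adjusted p = 0.627 with an estimated correlation and 0.281 under quantile normalization). Klf4 (-2.12 ± 0.58) and Klf2 (-2.39 ± 0.38) fell.

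The largest rises were in the chloride channel Ano1 (2.63 ± 1.23 to 78.4 ± 30.5 TPM), the chromatin protein Hmga1 (4.42 ± 0.816 to 102 ± 25.4 TPM), Ptprn (22.5 ± 8.48 to 369 ± 93.2 TPM), and alcohol dehydrogenase Adh1 (1.32 ± 0.533 to 33.0 ± 3.64 TPM). They also included Akr1b10 (2.21 ± 0.663 to 48.7 ± 21.3 TPM) and Cyp3a9_2, a copy of a duplicated symbol whose value is uncertain (0.682 ± 0.705 to 46.1 ± 19.4 TPM). The largest falls, with Fosb, Fos and Id1, were in Lmcd1 (342 ± 127 to 14.1 ± 2.64 TPM), Nkd2, an inhibitor of Wnt signalling (243 ± 119 to 10.2 ± 1.41 TPM), and the nuclear receptor Nr4a2 (185 ± 138 to 6.56 ± 2.99 TPM).

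In total 3384 genes passed (2347 higher, 1037 lower), 1095 at least 2-fold (643 higher, 452 lower). Under median-of-ratios scaling the split was 1715 higher and 1711 lower, and under quantile normalization 2050 and 1630. Without PDGF-BB library 3 the count was 2137.

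Myocd-LSD1 was set directly against PDGF-BB to test where the 2 conditions differed. Acta2 (2077 ± 611 against 2554 ± 606 TPM, adjusted p = 0.505, n = 4 and 3), Tagln (-0.53 ± 0.22, 0.0771), Myh11 (0.73 ± 0.44, 0.231) and Kdm1a (-0.12 ± 0.10, 0.390) did not pass. Cnn1 (51.0 ± 57.7 against 349 ± 63.9 TPM, adjusted p = 0.00163) and Myocd (-3.97 ± 0.26) were lower in Myocd-LSD1. Mitotic genes were lower, with Kif20a, a mitotic kinesin, at 22.8 ± 13.6 against 113 ± 14.2 TPM and Ccnb1 at 17.9 ± 11.9 against 71.1 ± 3.15 TPM. Early response genes were higher, with Fosb at 784 ± 264 against 26.5 ± 30.3 TPM and Fos at 2077 ± 487 against 228 ± 260.2 TPM. Klf4 averaged 490.4 ± 167 against 31.2 ± 11.3 TPM (log2 fold change 3.94 ± 0.58, adjusted p = 0.000168).

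The median log2 fold change of all genes was -0.10 here and -0.01 under median-of-ratios scaling. Counts adjusted over the list alone are in parentheses. Of proliferation genes 24 of 29 were lower (27), relative median -1.56 (limma camera adjusted p = 1.17e-07; adjusted p = 0.560 with an estimated correlation). Of early growth factor response genes 18 of 28 were higher and 1 lower (20 and 1), relative median 2.02 (adjusted p = 1.03e-10; adjusted p = 0.406 with an estimated correlation). Cholesterol genes had 18 of 25 lower (18; adjusted p = 1.55e-06; adjusted p = 0.512 with an estimated correlation). Interferon genes had 13 of 23 lower (13 lower and 2 higher; adjusted p = 0.00503; adjusted p = 0.633 with an estimated correlation), with Isg15 at -4.30 ± 0.64. Contractile genes had 15 of 30 lower and 1 higher (18 and 1; adjusted p = 4.81e-05; adjusted p = 0.495 with an estimated correlation), with Synpo2 at -3.38 ± 0.46 and Des at 1.46 ± 0.25.

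Amino acid and unfolded protein response genes were higher, 10 of 25 against 1 lower (12 and 1; adjusted p = 4.81e-05; adjusted p = 0.495 with an estimated correlation), led by Atf3 at 6.08 ± 0.65. So were TGF-beta and BMP genes, 9 of 24 against 2 (9 and 3; adjusted p = 0.000774; adjusted p = 0.406 with an estimated correlation), with Tgfbi at 5.76 ± 0.64 and Id1 at 5.06 ± 0.30. Cartilage and bone markers were also higher, 8 of 15 against 3 (8 and 4; adjusted p = 0.0107; adjusted p = 0.461 with an estimated correlation and 0.0588 under median-of-ratios scaling). Stem cell factors had 4 of 7 higher and 1 lower (5 and 1; adjusted p = 0.0405; adjusted p = 0.406 with an estimated correlation and 0.0900 under median-of-ratios scaling). Ribosomal proteins had 4 of 26 higher (0 alone; adjusted p = 0.000120; adjusted p = 0.633 with an estimated correlation). Mitochondrially encoded genes had 3 of 12 lower (2 alone; adjusted p = 0.0405; adjusted p = 0.686 with an estimated correlation and 0.0534 under median-of-ratios scaling). The mitochondrial list no longer passed without Myocd-LSD1 1 or 3 or PDGF-BB 2 (adjusted p = 0.132, 0.0866 and 0.453), nor did stem cell factors without Myocd-LSD1 3 or PDGF-BB 2 (0.0860 and 0.0543).

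The largest rises were Wfdc18, Uba1y and Ms4a18, the last listed at 0 in all 3 PDGF-BB libraries, and the largest falls Pcdh7, Nid1 and Cd180, a Toll-like receptor homologue (1.35 ± 1.42 against 145 ± 71.4 TPM). In all 3792 genes passed (1295 higher and 2497 lower in Myocd-LSD1), 1456 at least 2-fold (597 and 859). Under median-of-ratios scaling the split was 1848 and 2081, under quantile normalization 1899 and 2245, and 2242 genes passed without Myocd-LSD1 libraries 2 and 4.

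The genes called in both Myocd-LSD1 and PDGF-BB against control were then compared. In both conditions the genes that rose included Ano1 (log2 fold change 3.89 ± 0.31 and 4.43 ± 0.34), Akr1b10 (5.98 ± 0.30 and 3.89 ± 0.32), Adh1 (3.37 ± 0.42 and 3.89 ± 0.45), Mnda (4.81 ± 0.61 and 2.99 ± 0.66) and the nucleoside transporter Slc29a1 (2.91 ± 0.31 and 3.32 ± 0.33). Those that fell in both included Nkd2 (-5.88 ± 0.42 and -4.34 ± 0.46), troponin C, Tnnc1 (-5.52 ± 0.51 and -3.64 ± 0.55), Myh3, C1qtnf3 (-3.57 ± 0.64 and -3.42 ± 0.69) and Abi3bp (-4.89 ± 0.49 and -3.28 ± 0.53). Klf4, Atf3, Nfkbia (1.90 ± 0.60 and -2.64 ± 0.64), Rasd1 and Parm1 (2.50 ± 0.35 and -1.66 ± 0.38) rose in Myocd-LSD1 and fell with PDGF-BB. Cd180 (-3.53 ± 0.52 and 2.52 ± 0.56), Col15a1 (-2.48 ± 0.39 and 2.24 ± 0.42), the fatty acid desaturase Scd (-2.32 ± 0.41 and 1.84 ± 0.44), Il1rl1 and the chemokine Cxcl10 (-1.66 ± 0.60 and 2.93 ± 0.65) did the opposite.

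In the same direction 1393 genes were called (782 higher, 611 lower), and in opposite directions 43 and 94. Under median-of-ratios scaling the shared split was 619 higher and 944 lower, and under quantile normalization 751 and 902, so which direction prevailed depends on the scaling. Independent lists of these sizes would share 396 higher and 159 lower genes. Simulated unchanged groups set against the same controls shared 0.15 on average and 7 at most in 100 draws. With no gene changed, few genes pass the adjusted threshold, so this does not bound the part of the overlap due to the shared controls. With the controls split 2 and 2, so that the comparisons shared none, 687 to 795 genes were shared over 6 splits. Fewer controls in each comparison also lower the number of calls, so this count does not measure the part due to sharing. The correlation of the fold changes across genes, which are not independent replicates, was 0.43, against 0.41 on average and 0.93 at most in the simulations and 0.30 to 0.45 with the controls split. The covariance was 0.234 against a simulated 0.0204, a difference of 0.214. With the controls split it was 0.180 to 0.241, with a mean of 0.215, so most of it remained where no control was shared.

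**Figure D4:**
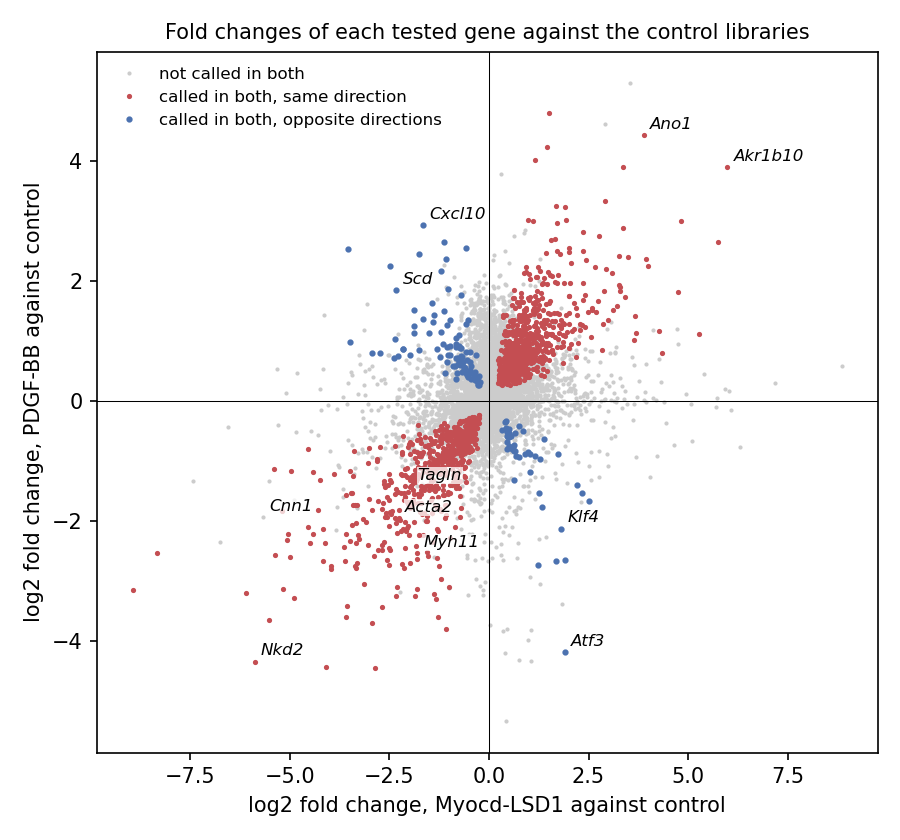
Log2 fold change of each tested gene in Myocd-LSD1 against control (horizontal axis) and in PDGF-BB against control (vertical axis), 1 point per gene, with genes called in both colored by direction. Of the called genes 1393 lie in the same direction and 43 and 94 in opposite directions.

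Myocd-LSD1 and Myocd-LSD1NF shared 162 genes called in the same direction against control (27 higher, 135 lower), with 19 and 3 in opposite directions. Pdpn (-5.32 ± 0.37 and -4.32 ± 0.37), Aebp1 (-3.66 ± 0.18 and -3.89 ± 0.18), Jup (-3.49 ± 0.23 and -3.46 ± 0.23), Nid1 (-7.43 ± 0.76 and -3.34 ± 0.76) and Actg2 (-3.49 ± 0.41 and -3.15 ± 0.41) fell in both lines. Dusp5, Loxl4 (1.72 ± 0.29 and 1.22 ± 0.29), Comp (1.86 ± 0.26 and 1.21 ± 0.26) and Magea11 (5.69 ± 0.23 and 1.08 ± 0.23) rose in both, as did Trappc2b_2, whose value is uncertain. The peripheral myelin protein Pmp22 (3.01 ± 0.16 and -1.68 ± 0.16), the transcription factor Eya1 (1.99 ± 0.23 and -1.71 ± 0.23), Ctsh, Gxylt2 and Rerg rose in Myocd-LSD1 and fell in Myocd-LSD1NF, and Mageh1, St6galnac3 (-0.92 ± 0.15 and 0.70 ± 0.15) and Aff2 did the opposite. Independent lists would share 9.8 higher and 32.5 lower genes. Simulated unchanged groups, which have the limit given above, shared 4.39 on average but 364 at most in 100 draws. The observed overlap with the controls split was 45 to 114, where fewer controls in each comparison also lower the number of calls. The count fell to 72 without control 2, 74 without control 1, 86 without Myocd-LSD1NF 2 and 105 without control 3. It was 65 with a filter at a mean of 5 TPM and 451 with array weights.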

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

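The tests of a raised run of neighbouring genes and of Y-linked transcripts were chosen only after the results were seen; the search for single libraries far from their group was planned. That search took each named gene and library measure in each group of 4, and marked a library whose gap to the nearest other exceeded the 95% limit of Dixon's ratio. It marked 28 of 405 sets of 4 values, where chance marks about 1 in 20, or 20.25. Of these, 15 fell on Myocd-LSD1NF 4.

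In Myocd-LSD1NF 4, Acta2 stood at 3979 TPM against 10729 to 11982 TPM in the other libraries of its group, Eln at 2292 against 7791 to 8543, Igfbp2 at 594 against 1116 to 1217, Pcdh7 at 51.0 against 105 to 112, Cdh11 at 4.63 against 41.0 to 46.4 and Rerg at 0.810 against 2.33 to 2.57. Higher than in the other libraries were Rgs5 (2269 TPM against 468 to 749), Epyc (281 against 29.3 to 71.2), Itga11 (163 against 34.8 to 50.6), C1qtnf3 (163 against 9.26 to 16.5), Mfap5 (117 against 5.25 to 9.82), Tfap2a (21 against 10.3 to 12.1), Wfdc18 (18.0 against 0 to 0.470), Tgfbi (14.4 against 0.560 to 0.850) and Gxylt2 (1.98 against 0.470 to 0.650). Myh3 stood at 5.43 TPM in Myocd-LSD1NF 1 against 0.40 to 0.98 in the others.

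Among the Myocd-LSD1 libraries, library 3 was apart in Ctgf (6519.7 TPM against 3850 to 4093), Lmcd1 (148 against 21.1 to 38.6) and Nkd2 (7.29 against 1.71 to 2.31), library 1 in Igf2bp3 (20.9 against 15.1 to 16.0) and Rgs5 (1.79 against 0.210 to 0.240), and library 4 in Rhox5 (16.8 against 7.95 to 9.24). Among the controls, library 1 was apart in Cdkn1a (272 TPM against 129 to 140.3), Scd (49.0 against 27.3 to 30.9) and Mx2 (6.79 against 0.580 to 1.42), library 2 in Nkd2 (419.6 against 162 to 196), library 3 in Postn (4893 against 9374 to 10218) and library 4 in Psat1 (53 against 9.21 to 15). No explanation was tested for these.

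In Myocd-LSD1NF libraries 1 to 3 a run of 506 neighbouring genes of 1 chromosome, from Spon1 to Grk5 with Acta2 among them, stood above control, with medians of 0.35, 0.44 and 0.16 on the log2 scale and -0.06 in library 4. With each library centred on its median they were 0.38, 0.42, 0.32 and -0.04, and the values below are centred except where scaling is named. Only the start of this run of genes was fitted, and its end is the last placed gene of the chromosome by construction. The tables argue against the expression level of these genes as the cause, since 10000 random sets of genes of matched level reached at most 0.0363 in any of the 3 libraries, and against scaling, since the run stood at 0.16 or more in the deposited values and at 0.27 or more when these were scaled in either way. Extra copies of the segment in the cells of these libraries may account for it, since each of 4 equal parts of the run was raised, the lowest by 0.25. An effect of the fusion protein of the group cannot be told apart from this, since library 4, at -0.0382, is 1 library.

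The Y-linked genes Eif2s3y, Kdm5d and Uba1y differed between the Myocd-LSD1 libraries by 3.76, 3.44 and 4.12 times, low in libraries 2 and 4, where Cnn1 was low as well. Fewer cells with a Y chromosome in libraries 2 and 4 may account for the Y-linked genes, since the ratio of Uba1y to Eif2s3y varied only 1.23 times over the 4 libraries. The tables argue against scaling, since Eif2s3y stayed at 53.8% of the control mean or less in libraries 2 and 4 after scaling. Cells like the controls within libraries 1 and 3 are argued against by 5 genes abundant in control, Rgs5, Rgs4, Pcdh7, Nid1 and Cd9, that stayed under 1% of control in all 4 libraries while Cnn1 stood at 4.72% and 9.54% in libraries 1 and 3. A difference between cultures of the line stays open, untested.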

How the results depend on the processing

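The removal of Myocd-LSD1 libraries 2 and 4 together and of the genes of the raised run were tests chosen only after the results were seen; the other alternatives were planned. The numbers of called genes stayed within 1.5 times the reported ones in every setting for Myocd-LSD1 against control (2984 to 5455, reported 3936) and for Myocd-LSD1 against Myocd-LSD1NF (2896 to 5021, reported 3877). The correlation of fold changes between Myocd-LSD1 and PDGF-BB, 0.43, ranged from 0.39 to 0.49, and from 0.40 to 0.46 when each library was left out. Of 426 results for single genes named by the rule, 411 were calls, of which 323 stayed calls in every setting and 334 in every setting that left out no single library; 0 reversed. With TPM, the depth behind low values cannot be read, so its limit on these calls is unknown.

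A pseudocount of 5, which shrinks the fold changes of low genes by construction, gave 811, 63, 682, 635 and 826 genes changed at least 2-fold in the 5 comparisons in the order of the report. A filter at a mean of 5 TPM, which tests fewer genes, gave 964 for Myocd-LSD1 against control, 60 for Myocd-LSD1NF against control and 850 for Myocd-LSD1 against Myocd-LSD1NF, 110 genes called for Myocd-LSD1NF against control, and 65 shared by both lines. Array weights gave 919 genes called and 253 changed at least 2-fold for Myocd-LSD1NF against control, 451 shared by both lines and 2093 shared by Myocd-LSD1 and PDGF-BB. Fitting the compared groups alone gave 176 for Myocd-LSD1NF against control, with fewer samples to estimate the spread. Without Myocd-LSD1 libraries 2 and 4, Myocd-LSD1 against PDGF-BB gave 2242, with fewer samples. Without the raised run Myocd-LSD1NF against control gave 254. Apart from the settings whose construction shows it, the cause was not tested.

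Lists passing camera fell to 0 in all 5 comparisons with an estimated correlation. The rotation test fry, which tests each list by itself, gave 10 for Myocd-LSD1 against control, 2 for Myocd-LSD1NF against control, 12 for Myocd-LSD1 against Myocd-LSD1NF and 18 for Myocd-LSD1 against PDGF-BB. For Myocd-LSD1 against control, with 3 reported, 8 lists passed without a filter, 5 under quantile normalization, 6 with the replicate block, 8 with array weights, 8 with the compared groups alone and 7 without Myocd-LSD1 libraries 2 and 4; the cause was not tested. With the replicate block, 4246, 342, 4232, 3565 and 3719 genes passed in the 5 comparisons. Whether replicate numbers pair the libraries stays open. Of 21 pairs of equal number in different groups, 11 correlated above 0.1 in their deviations from the group means (-0.225 to 0.576). Among control and the 2 lines, numbers 1 and 3 correlated at 0.184 to 0.576 and number 4 at 0.0158 to 0.301. Number 2 went the other way, at -0.163 to -0.0715. Of 15 libraries 7 correlated best with 1 of their own number.

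Leaving out each library in turn gave 109 to 312 genes for Myocd-LSD1NF against control (109 without control 1, 112 without control 2, 128 without Myocd-LSD1NF 2 and 171 without control 3), and 80 to 174 changed at least 2-fold (80, 86 and 92 without the first 3 of these). The overlap of both lines ranged from 72 to 198 (74 without control 1, 72 without control 2, 86 without Myocd-LSD1NF 2 and 105 without control 3). PDGF-BB against control gave 2137 to 2993 (2137 without PDGF-BB 3). The lists passing camera numbered 3 to 7 for Myocd-LSD1 against control (7 without Myocd-LSD1 1, 6 without Myocd-LSD1 4, 6 without control 3, 5 without control 4), 5 to 11 for Myocd-LSD1NF against control (5 without control 2) and 3 to 7 for Myocd-LSD1 against Myocd-LSD1NF (7 without Myocd-LSD1NF 3). Only fewer samples distinguish these fits by construction; why these libraries matter was not tested.

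Calls of 10 lists, besides ribosomal proteins, were lost when 1 library was left out. In Myocd-LSD1NF against control these were the contractile list without Myocd-LSD1NF 4 (adjusted p = 0.104), cholesterol without Myocd-LSD1NF 4 (0.172), early growth factor response without control 2 (0.0520), TGF-beta and BMP without Myocd-LSD1NF 4, control 1 or control 2 (0.204, 0.125 and 0.0783) and amino acid response without the same 3 (0.269, 0.103 and 0.415). In PDGF-BB against control they were glycolysis without control 2 or PDGF-BB 2 (0.0508 and 0.0521) and amino acid response without control 4, PDGF-BB 1 or PDGF-BB 2 (0.465, 0.135 and 0.0536). Mitochondrially encoded genes lost their call in Myocd-LSD1 against Myocd-LSD1NF without Myocd-LSD1 1 or 3 or Myocd-LSD1NF 1 or 4 (0.145, 0.119, 0.104 and 0.0974) and in Myocd-LSD1 against PDGF-BB without Myocd-LSD1 1 or 3 or PDGF-BB 2 (0.132, 0.0866 and 0.453), and stem cell factors there without Myocd-LSD1 3 or PDGF-BB 2 (0.0860 and 0.0543).

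The direction of 3 list results turned. Ribosomal protein genes, higher in Myocd-LSD1NF than in control, had an adjusted p of 0.611 and the other direction without Myocd-LSD1NF 3, and no longer passed without control 1 or control 2 (0.336 and 0.717), over a range of 2.49e-05 to 0.877 among alternatives. Endothelial markers in Myocd-LSD1 against Myocd-LSD1NF had 0.0266 with fry (range 0.0266 to 0.9996), and proliferation genes in Myocd-LSD1 against control 0.0210 without Myocd-LSD1 libraries 2 and 4 (range 0.0210 to 0.988), each the other way from a reported result that had not passed. The cause was not tested.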

Other observations

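The tests here of genes switched off or on, of Hox genes and of germ cell genes were chosen only after the results were seen, as were their genes; the other splits of the libraries were planned. In Myocd-LSD1, 46 genes stood at 5 TPM or more in all 4 controls and under 1 TPM in all 4 libraries of the line, against 2 in Myocd-LSD1NF and 5 with PDGF-BB. They included Ptn, pleiotrophin (mean 55.1 TPM in control and 0.305 in Myocd-LSD1), the tetraspanin Cd9 (50.5 and 0.0775 TPM), the homeodomain protein Hopx (40 and 0.0900 TPM) and phospholamban, Pln (12.4 and 0.590 TPM). Means under the control mean were not confined to Myocd-LSD1. In Myocd-LSD1NF and PDGF-BB, Ptn averaged 18.0 and 23.3 TPM, Cd9 12.4 and 19.5, Hopx 17.4 and 6.85, and Pln 14.0 and 2.32. In the other direction 31 genes went from under 1 TPM in each control to 5 TPM or more in each Myocd-LSD1 library, against 1 in Myocd-LSD1NF and 7 with PDGF-BB. Among them were the transcription factor Tfec (0 TPM in the controls and a mean of 52.3), Angpt1, the angiopoietin ligand of endothelial Tie receptors (0.0600 and 33.5 TPM), caspase 1, Casp1 (0.0625 and 18.8 TPM), and the RNA-binding protein Igf2bp3 (0.167 and 16.8 TPM).

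Of 39 Hox genes, the factors of position along the body axis, 19 were tested. In Myocd-LSD1 against control 4 rose and 6 fell, 0 passed in Myocd-LSD1NF, and with PDGF-BB 1 rose and 1 fell. Hoxd13 fell from a mean of 110.2 to 28.6 TPM (log2 fold change -2.20 ± 0.37, adjusted p = 0.000317 by limma) and Hoxc6 from 9.45 to 1.98 TPM (-1.81 ± 0.17), while Hoxa13 rose from 0.285 to 4.5 TPM (2.01 ± 0.25) and Hoxb7 from 5.67 to 14.4 TPM (1.21 ± 0.14). As a set they did not pass limma camera (p = 0.107; p = 0.344 with an estimated correlation). Against Myocd-LSD1NF, 4 were higher and 7 lower in Myocd-LSD1, and the set was lower by camera (p = 0.0125) but not with an estimated correlation (p = 0.154).

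Among the genes switched on was Rhox5, a homeobox gene of the testis (0.0900 TPM in control and 10.6 in Myocd-LSD1), which raised the hypothesis that germ cell genes as a class may have been released. Of 55 listed germ cell genes found in the table, only 2, Rhox5 and Tex101, reached 1 TPM in any Myocd-LSD1 library, and Tdrkh fell. The mean was higher than in control in 12 (21.8%; exact 95% limits 11.8% and 35.0%), lower in 14 and equal in 29. The share counts equal means as not higher, which lowers it, so its limits do not decide the question. Only 3 listed genes passed the filter and were tested, of which 2 rose and 1 fell. The tables argue only against a release of most listed genes to 1 TPM, since 2 of 55 reached it in any Myocd-LSD1 library. A rise that stays under 1 TPM is not covered, and genes outside the list were not weighed. Why single members rose stays open, untested.

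For each comparison the calls were counted in all 35 splits of its libraries into groups of the same sizes. For the numbers of called genes 1 split, the real 1, gave as many: 3936 against 32 in the highest other split for Myocd-LSD1 against control, 270 against 3 for Myocd-LSD1NF against control, 3877 against 264 for Myocd-LSD1 against Myocd-LSD1NF, 3384 against 177 for PDGF-BB against control and 3792 against 2552 for Myocd-LSD1 against PDGF-BB. The same held for changes of at least 2-fold, in the same order 1475 against 15, 150 against 3, 1286 against 138, 1095 against 108 and 1456 against 1011. Chance is not excluded by this, since 1 of 35 is the smallest share that can be reached. Splits that mix the groups also turn the group difference into spread, which lowers their counts by construction. Where replicates are technical, the splits say nothing of differences between cultures. The count of 2552 came from the split that sets Myocd-LSD1 1 with the PDGF-BB libraries. For the number of lists passing camera chance cannot be excluded either: 33, 18, 34, 7 and 3 of the 35 splits gave as many as the real 3, 9, 4, 11 and 11, with 11, 13, 9, 13 and 11 in the highest other split.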
